A study of Mus musculus with 8 samples.

How the data were processed

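RNA of sorted VAT ILC2s was measured by sequencing of full-length cDNA in 8 libraries, 4 per diet. Per the labels' protocols, total RNA was taken up in Trizol, cDNA was made with the SMART-Seq HT kit and libraries were built with a transposase kit (TruePrep). Such a library does not mark the strand, so reads of a gene and of an antisense or overlapping partner cannot be told apart. The submitters' processing notes name HISAT2, Cufflinks and the mouse build mm10. Versions, the annotation and the filters are not given in the sources used here.

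The deposited values are FPKM by the column names (fragments per kilobase of gene, scaled to library size), per the file headers, with 1 value per gene and library for 39527 genes. The values show 2 departures from plain FPKM. In 14605 genes, 1483 of them protein coding, the values are below 0 or at 0 in every library, as if divided by a gene length of -1. No gene holds both signs, and 815 genes are at 0 throughout. These genes cannot enter a log2 scale and are left out of the main test. Second, within a library the value of 1 read, apart from gene length, takes 10 sizes. With the genes in the order of their identifiers the size repeats every 10 rows, in 100% of the values below 0, and it differs between libraries only by where the repeat starts. The sizes range from 0.863 to 1.18 around a geometric mean of 1. The starts are those of a list of 10 factors laid down the columns of a table of 39527 rows, with the 8 libraries at 8 of its 10 positions. The factor at each library's own position also appears in that library's overall divisor, to within 0.404%. The factor therefore differs between genes for no reason of their own, and shifts a gene's log2 difference between the diets by -0.08 to 0.09. It was kept in the main test, which uses the values as deposited, and divided out in an alternative.

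Once the factor was known, whole reads followed. For genes above 0 the length was taken as the smallest whole number of at least 20 that made the values of all 8 libraries whole multiples of 1 read (relative tolerance 1e-06), and this was found for 100% of 24107 genes. With the factor of the next row in its place, 0 of 1000 genes drawn from those above 0 in all libraries gave whole reads. A gene whose reads share a divisor comes out too low. Recovered reads came to 9005363 to 15752815 per library, which sets the counting precision, and genes with values below 0 held 1.73% to 2.50% of them. Tested on a simulated table with 10 recycled factors, the same code found all 10.

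Genes were tested at 1 FPKM or more in at least 4 of the 8 libraries with no value below 0, which left 11483 genes (10499 protein coding). Values were taken as log2(FPKM + 1). limma 3.58.1 in R 4.3.3 was fitted with diet as the only term, with eBayes trend and robust options, and p-values were two-sided with Benjamini-Hochberg adjustment at 0.05. Fold changes are high-fat minus normal diet. In simulated libraries with 200 changed genes among 11483, this test recovered 78% of 2-fold and 98% of 4-fold changes with 4.86% of calls false. Of 5 shifted simulated lists camera called 5, and of 15 unshifted lists 0. The simulated genes varied independently of one another. In the libraries the estimated correlation was 0.765 within the mitochondrially encoded list and 0.631 within the cytosolic ribosome list. The simulation therefore gives no error rate for camera on lists whose genes vary together. The deposited values are not counts, so tests that need counts were not used on them. The only such test was run on recovered reads (below), with a filter and library sizes meant for counts.

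A total of 38 gene lists with 997 members, covering the pathways of the title, ILC2 biology and markers of other cell types that a sort gate could hold, were fixed before the data were examined, as were the tests, the rule for named genes and all alternatives not said to be added later. The 34 lists with at least 5 tested members were tested with limma camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. The genes named are the 10 largest rises and 10 largest falls among called genes with no overlap between the diets and a mean in the upper part of the tested genes, without predicted or unnamed genes. To these were added up to 4 called members of each list by size, or for a list with none the 2 most expressed, and a fixed panel of Stk11, Prkaa1, Ppargc1a, Gata3, Il1rl1, Il7r, Klrg1, Il5, Il13, Areg, Pdcd1, Ifng and Tbx21. This gave 94 genes, 60 of them called, and another gene that the rule takes is not reported here. A gene named outside the rule is said to be chosen after its values were seen. Of the tested genes, 16 carry symbols that a spreadsheet had turned into dates, and none of these was among the genes named. Coordinates come from GENCODE M21 (mm10) by gene identifier, where 11468 of the tested genes were found.

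Settings fixed before the data were examined were quantile normalization, equal library medians, no filter, a filter at 5 FPKM, a pseudocount of 0.1, limma without trend and robust, array weights, a replicate block and each library left out. Added after seeing the data were the factor divided out, limma voom on recovered reads (at least 10 reads in 4 libraries, library sizes by the median of ratios), library 2 of both diets left out, and the mean of the mast cell list or of the T cell list as a covariate. Single values were compared by exact two-sided permutation of the 8 libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the recovery of reads, tables and figures.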

Results

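Group 2 innate lymphoid cells (ILC2s) are tissue-resident lymphocytes without antigen receptors of their own that secrete type 2 cytokines, and in visceral fat they are a main source of interleukin-5. RNA was profiled in ILC2s sorted from the epididymal visceral adipose tissue (VAT) of male wild-type C57BL/6 mice. There were 4 libraries from mice on a normal diet and 4 from mice on a high-fat diet. The diets ran for 8 weeks from 6 weeks of age, and the cells came from mice 14 weeks old. The title of the series places the work in a study of LKB1, the kinase that activates AMPK, and of mitochondria in adipose ILC2s. The comparison made here asks which transcripts differ between the diets in these cells. The labels do not say whether the libraries came from separate animals or pools, so p-values measure the spread between these libraries, which may be technical.

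The high-fat libraries are called H1 to H4 here and the normal-diet libraries N1 to N4. The reads recovered from the deposited values came to 14435400, 9005363, 13404162 and 15752815 in H1 to H4 and to 12272413, 14969666, 13499966 and 15225871 in N1 to N4. Per library, 10763 to 13663 genes reached 1 FPKM. The 100 genes with the most reads held 27.7% to 28.3% of the reads on the high-fat diet and 28.8% to 30.2% on the normal diet. Between pairs of libraries of the same diet, the correlation of log2 values across the tested genes ran from 0.957 to 0.983 on the high-fat diet and from 0.972 to 0.978 on the normal diet. Between the diets it ran from 0.952 to 0.974, which overlaps both ranges. H2 correlated at 0.957 to 0.970 with the other high-fat libraries and at 0.952 to 0.966 with the normal-diet libraries. The first principal component held 28.2% of the variance. It held all high-fat libraries above 0 (3.17 to 35.2) and all normal-diet libraries below 0 (-35.4 to -7.63), with H2 and N2 at the ends and the other 6 libraries between -11.4 and 18.2. The second component held 25.9% and did not part the diets. On it H2 stood at -24.3, the normal-diet libraries at -18.0 to -1.52 and H1, H3 and H4 at 10.2 to 28.5. No pair of libraries of the same diet held the same reads within sampling noise: the chi-square per gene was between 8.84 and 24.4.

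High-fat diet changed 328 of 11483 tested genes, and 216 of them fell while 112 rose. The number of calls in each list below is to be read beside that share. Among the called genes with no overlap of the diets and a mean in the upper part of the tested genes, the largest fall was that of Il5, the cytokine that sustains eosinophils, and the largest rise that of Fabp4, a fatty acid carrier of endothelial cells, adipocytes and macrophages. Among the 328 genes, the libraries of the diets did not overlap for 321. Of all tested genes 11.1% did not overlap, where chance gives 2.86%. The test was limma on log2(FPKM + 1) with Benjamini-Hochberg adjustment, and fold changes are on that scale, which understates the change of low genes. When the libraries were scaled by quantile normalization, 226 genes rose and 204 fell, and at equal library medians 172 rose and 305 fell, so the excess of falls was absent under the first and held under the second. Without H1, H2, H3 or H4 the count was 200, 535, 151 or 129 genes, and without N1, N2, N3 or N4 it was 197, 183, 298 or 317. Without both H2 and N2, a setting chosen after seeing the data, 250 genes rose and 222 fell. The T cell list was called higher by camera at the preset correlation but not at an estimated one (adjusted p = 0.740), and no member passed (below). With its mean as a covariate, also chosen after seeing the data, 29 genes passed.

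**Figure D1:**
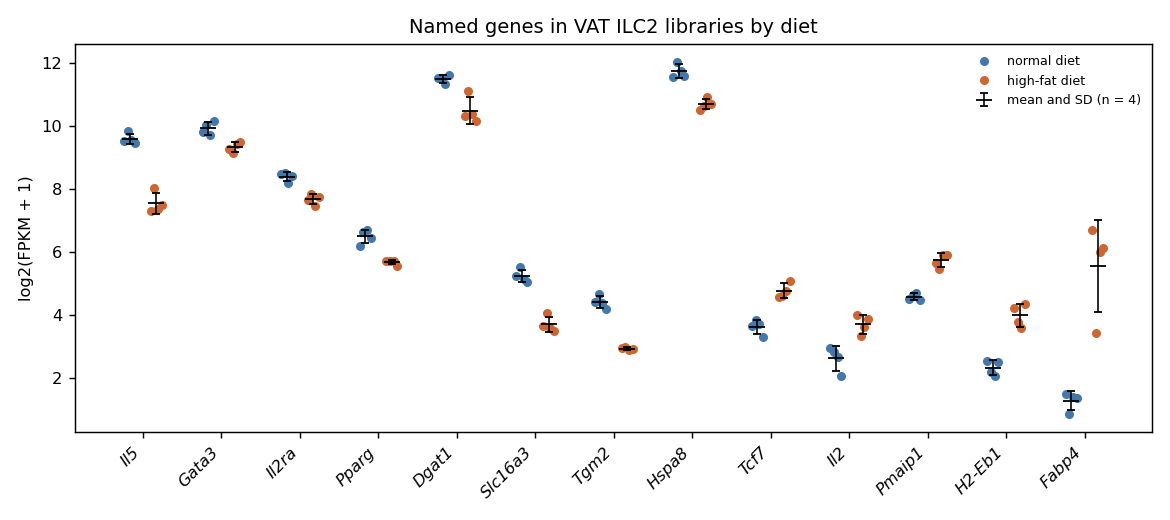
Values of 13 named genes in the 8 libraries, with log2(FPKM + 1) on the vertical axis and genes on the horizontal axis. Blue points are the 4 normal-diet libraries and orange points the 4 high-fat libraries, with the mean and SD in black. Il5 averaged 780 FPKM on the normal diet and 189 FPKM on the high-fat diet, and Fabp4 1.45 and 61.3 FPKM.

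Among type 2 cytokines, Il5 (ENSMUSG00000036117, chromosome 11, 53720794 to 53725106 in mm10) fell from 780 ± 92.7 FPKM to 189 ± 48.1 FPKM (SD, n = 4 each). Its log2 fold change was -2.06 with a standard error of 0.17 (limma, adjusted p = 7.63e-05). Il13, which drives goblet cells and alternative macrophage activation, stood at 8.63 ± 2.40 and 7.24 ± 1.80 FPKM on the normal and high-fat diets and did not pass (log2 fold change -0.22, adjusted p = 0.618). Areg, an epidermal growth factor family member, was at 600 ± 157 and 744 ± 148 FPKM (0.33, adjusted p = 0.417). Furin, a proprotein convertase, fell by 0.75 on the log2 scale and Il2, a lymphocyte growth factor, rose by 1.08. Of the 21 tested members of the type 2 effector list 1 rose, 2 fell and 18 did not pass, with 2 higher and 4 lower when adjusted over the list alone. The call of Il5 held without each library in turn, between -2.22 and -1.98, and that of Il2 ended without H4 (adjusted p = 0.0521).

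Most genes of ILC2 identity did not pass, and of those that did more fell than rose. Gata3 (ENSMUSG00000015619, chromosome 2, 9857078 to 9890034), the transcription factor that maintains ILC2s, went from 982 ± 139 to 648 ± 66.6 FPKM (log2 fold change -0.59, standard error 0.15, adjusted p = 0.0449). Il2ra, the high-affinity receptor chain, fell by 0.72, Il2rg by 0.64 and Zbtb16, which marks innate lymphoid precursors, by 0.85. Tcf7, a transcription factor of early and stem-like lymphocytes, rose from 11.4 ± 1.88 to 26.4 ± 4.74 FPKM (1.14, adjusted p = 0.00296). Of the 24 tested identity genes 1 rose, 5 fell and 18 did not pass (2 higher and 7 lower adjusted over the list alone). That is a larger share of calls than the 328 of 11483 over all tested genes, a difference that was not tested. The list as a whole did not shift in 1 direction (camera, adjusted p = 0.159, and in none of 16 other settings). The mixed test of fry, for changes in either direction, gave it adjusted p = 2.46e-05, but most of the tested lists passed that test. Il1rl1, the interleukin-33 receptor, was at 356 ± 59.0 and 282 ± 13.7 FPKM (-0.32, adjusted p = 0.273), Klrg1 at 817 ± 73.3 and 588 ± 132 FPKM (-0.49, adjusted p = 0.124) and Il7r at 184 ± 23.0 and 229 ± 30.4 FPKM (0.31, adjusted p = 0.293). Il2rb, another chain of the interleukin-2 receptor, chosen after its values were seen, fell by 0.63. The calls of Gata3 and Il2rg each ended without H1, H2, H3, H4, N1, N2 or N4 (adjusted p up to 0.113 and 0.123) and under quantile normalization. That of Zbtb16 ended without H1, H3, H4, N1 or N4 (up to 0.0752) and that of Il2ra without H3 (0.0713).

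Most genes of lipid handling and of its receptors did not pass. Pparg, the nuclear receptor for fatty acid ligands, fell from 90.0 ± 13.1 to 50.4 ± 2.65 FPKM (log2 fold change -0.81, adjusted p = 0.00916). Dgat1, which makes triglyceride from diacylglycerol, fell from 2915 ± 241 to 1495 ± 480 FPKM (-1.01, adjusted p = 0.0104). Soat1, which esterifies cholesterol, fell by 1.35 and Mvk, an enzyme of the mevalonate pathway, by 1.53. Fabp4 (chromosome 3, 10204088 to 10208576) rose from 1.45 ± 0.45 to 61.3 ± 38.9 FPKM (4.29, standard error 0.70, adjusted p = 0.0270). Among the high-fat libraries it was lowest in H2, at 9.68 FPKM against 62.5 to 104 FPKM. In the list of fatty acid uptake, storage and oxidation 1 gene rose, 2 fell and 33 of 36 did not pass (5 higher and 3 lower adjusted over the list alone). Of the cholesterol and SREBP targets 1 of 24 fell (2 adjusted over the list alone) and none rose. Among the 20 tested receptors for neural and lipid mediators Calcrl, a receptor for calcitonin gene-related peptide that endothelial cells also carry, rose by 0.94, and Ret and Pparg fell, Ret by 1.04 (1 higher and 5 lower adjusted over the list alone). Endothelial cells carry both Fabp4 and Calcrl, and some other transcripts of those cells were higher as well (below). The call of Fabp4 ended without H1, H3, H4, N1, N2, N3 or N4 (adjusted p up to 0.102), with the fold change between 3.90 and 5.004, and also on recovered reads (0.264) and with the T cell covariate (0.108), both chosen after seeing the data. The call of Ret ended without H3, H4 or N1 (up to 0.0654) and that of Calcrl without H1 or H3 (up to 0.0579). Quantile normalization ended the calls of Dgat1 and Mvk.

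Camera at the preset correlation called the lists of glycolysis and of nutrient genes lower relative to the other genes, though most members did not pass. Slc16a3, a lactate exporter, went from 37.0 ± 5.53 to 12.1 ± 2.41 FPKM (log2 fold change -1.54, standard error 0.16, adjusted p = 0.000584). Slc2a3, a glucose transporter, fell by 0.64. Of 23 glycolysis genes 2 fell, 21 did not pass and 20 had a fold change below 0 (4 lower adjusted over the list alone). The median log2 fold change was -0.23 (camera, preset correlation 0.01, adjusted p = 0.00143), with adjusted p = 0.740 with an estimated correlation and 0.0213 under quantile normalization. In the amino acid, polyamine and mTORC1 list Vegfa fell by 1.18, Slc7a5, a large neutral amino acid transporter, by 1.01 and Rheb, the activator of mTORC1, by 0.70. These were 3 of 24 tested genes, with 8 lower adjusted over the list alone (camera adjusted p = 0.00226, with adjusted p = 0.740 with an estimated correlation and 0.107 under quantile normalization). The call of Slc2a3 ended without H1, H3, H4, N2 or N3 (adjusted p up to 0.120), that of Slc7a5 without H3, H4, N1 or N3 (up to 0.0699) and that of Rheb without H3, H4, N1 or N2 (up to 0.0715).

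No gene of the LKB1 and AMPK axis passed among 29 tested. Stk11 (chromosome 10, 80115803 to 80130682), which encodes LKB1, was at 17.1 ± 2.19 FPKM on the normal diet and 12.3 ± 1.76 FPKM on the high-fat diet, without overlap between the diets (log2 fold change -0.46, standard error 0.16, adjusted p = 0.131). It passed in 1 of 21 other settings, the test on recovered reads chosen after seeing the data (adjusted p = 0.0365, and up to 0.304 over the other settings). Prkaa1, a catalytic subunit of AMPK, was at 6.99 ± 0.80 and 8.79 ± 1.80 FPKM (0.28, adjusted p = 0.428). Sik1, a kinase activated by LKB1, was at 116 ± 24.5 and 113 ± 7.74 FPKM, and Crtc2, a target of such kinases, differed by -0.27 on the log2 scale (adjusted p = 0.488). The list did not shift in 1 direction (camera adjusted p = 0.293). The mixed test of fry gave it adjusted p = 0.00684, and values under 0.05 for most of the tested lists. Ppargc1a, a driver of mitochondrial biogenesis, lay under the filter, at 0.449 to 1.90 FPKM over the 8 libraries.

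Few mitochondrial genes passed. None of 10 tested mitochondrially encoded genes passed, and all 10 had a fold change below 0, with a median of -0.37 (1 lower adjusted over the list alone). mt-Cytb was at 845 ± 111 and 640 ± 176 FPKM on the normal and high-fat diets (-0.44, adjusted p = 0.259) and mt-Nd1 at 924 ± 146 and 777 ± 239 FPKM. None of 76 nuclear-encoded subunits of oxidative phosphorylation passed, with a median of -0.12, and Atp5b differed by -0.02 and Cox6a1 by -0.13, both above 0 under quantile normalization. Camera called both lists lower (adjusted p = 0.0370 and 0.0272), with adjusted p = 0.740 and 0.777 with an estimated correlation. Under quantile normalization they had adjusted p = 0.146 and 0.843, the second in the upward direction, and the calls held in 8 and 7 of 16 other settings. Neither list passed without H2 (0.447 for both), where mt-Nd1 differed by -0.05 and mt-Cytb by -0.23, nor without both H2 and N2 (0.400 and 0.750). The TCA cycle list, with Mdh2 and Sdhb at -0.35 and -0.16, did not pass (camera adjusted p = 0.227, and called in 1 of 16 other settings), nor did the mitochondrial ribosome (0.773). In the latter list Mrps35 rose by 0.60, a call that ended without H1, H3, H4, N1, N2, N3 or N4 (adjusted p up to 0.122). In the list of mitochondrial dynamics and mitophagy (camera adjusted p = 0.221) no gene of 33 passed. Its most expressed members were Sqstm1, an autophagy receptor, at 1154 ± 369 and 671 ± 85.0 FPKM (-0.74, adjusted p = 0.0534, and past the threshold in 7 other settings), and Map1lc3b at -0.28. The mixed test of fry gave adjusted p = 0.0081 for this list, 0.0061 for the mitochondrial ribosome and 0.213 for the TCA cycle.

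Some genes of activation, of NF-kB and of protein folding fell, but their lists did not shift in 1 direction in any of 17 settings. The mixed test of fry gave adjusted p = 0.000316 for NF-kB, 4.06e-05 for the immediate early and dissociation response and 0.000746 for the unfolded protein response. Most of the tested lists passed the mixed test, so these values do not set these lists apart. Nfkb2, Relb and Nfkb1, subunits of NF-kB, fell by 0.74, 0.67 and 0.63, and 3 of 21 tested genes of that list passed (4 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.221). Hspa8, a constitutive chaperone, fell from 3455 ± 557 to 1673 ± 200 FPKM (log2 fold change -1.04, adjusted p = 0.00296). Egr2, Egr3 and Dnajb1 fell by 0.88, 0.82 and 0.63, so that 4 of 28 genes of the immediate early and dissociation response fell and none rose (1 higher and 4 lower adjusted over the list alone). Xbp1 and Hspa9 of the unfolded protein response fell by 0.73 and 0.60, which were 2 of 25 genes (2 lower adjusted over the list alone). Srxn1, which repairs oxidised peroxiredoxins, fell by 1.28 (adjusted p = 0.00187) and was the only member called of 23 antioxidant genes (4 lower adjusted over the list alone). Tgm2, a transglutaminase, fell from 20.4 ± 2.97 to 6.61 ± 0.21 FPKM (-1.48, adjusted p = 0.000332). The calls of Nfkb2 ended without H3 or H4, Relb without H1, H3, H4, N1, N2 or N4, Nfkb1 without H1, H3, H4, N2 or N4, Egr2 without H1, N2 or N3 and Egr3 without H1, H4, N2, N3 or N4 (adjusted p up to 0.0535, 0.102, 0.0918, 0.0732 and 0.0912). Quantile normalization ended the calls of Relb, Nfkb1 and Dnajb1. Those of Dnajb1 also ended without H4, Xbp1 without H3, H4, N1 or N2 and Hspa9 without H1, H3, H4, N2 or N4 (up to 0.0633, 0.0898 and 0.0715).

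No gene of the inhibitory receptor list was called higher over all tested genes. Pdcd1, which encodes PD-1, was at 645 ± 110 and 758 ± 137 FPKM (log2 fold change 0.23, adjusted p = 0.511). Lilrb4a fell by 0.93 (adjusted p = 0.00330) and Tnfrsf9, a costimulatory receptor, by 0.66, and these were the 2 called genes among 20 of the list (2 higher and 4 lower adjusted over the list alone). Lilrb4a has a close paralog, so reads of the pair can be split by the counting. Il12rb1, a chain of the interleukin-12 receptor, fell by 0.87 and was the only call among 12 genes of type 1 plasticity (4 higher and 5 lower adjusted over the list alone). Ifng was at 0.434 to 1.93 FPKM on the high-fat diet and 0 to 1.59 FPKM on the normal diet, and Tbx21 at 0.304 to 1.48 and 0 to 0.810 FPKM, both under the filter. Of 7 genes of the type 17 list Nrp1, a semaphorin and VEGF co-receptor, rose by 1.31 and Lta by 0.64 (2 higher adjusted over the list alone). None of 21 interferon response genes passed, with B2m at 0.37 and Psmb8 at -0.13 (mixed test of fry for the list, adjusted p = 0.0201). The call of Tnfrsf9 ended without H1, H3, N1, N3 or N4 (adjusted p up to 0.126) and under quantile normalization, and that of Lta without H1, H3, H4, N1 or N4 (up to 0.0963).

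Other named genes were taken by size or from the apoptosis, migration and natural killer lists. Pmaip1, a pro-apoptotic protein, went from 22.9 ± 1.81 to 52.8 ± 8.20 FPKM (log2 fold change 1.16, adjusted p = 0.00187). Bbc3, another pro-apoptotic gene, fell by 1.05, and no other member of 23 apoptosis genes passed (1 higher and 2 lower adjusted over the list alone). Ubash3a and Sit1, adaptors of antigen receptor signalling, rose by 1.12 and 1.09, and Ly6g5b, Mns1 and Ttc39c rose by 1.59, 1.14 and 1.07. Cd24a, Acbd7 and Fbxl21 fell by 1.94, 1.39 and 1.35. Txk, a Tec family kinase, fell by 1.07. Itgb1, an integrin chain, rose by 0.69 and Cxcr6, a chemokine receptor of tissue residence, fell by 0.69, with 20 of 22 migration genes not past the threshold (1 higher and 5 lower adjusted over the list alone). With the T cell covariate, of the genes of this paragraph only Pmaip1 and Ubash3a stayed past the threshold, and Sit1 stood at 0.63 (adjusted p = 0.157). The calls of Sit1 ended without H1, H3, H4, N1 or N2, Cd24a without H3, H4 or N1 and Acbd7 without H3, N1 or N2 (adjusted p up to 0.0655, 0.0715 and 0.0550). Those of Itgb1 ended without H1, H3, H4, N1, N3 or N4 and Cxcr6 without H3, H4, N1 or N2 (up to 0.114 and 0.0981).

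Camera at the preset correlation called the cytosolic ribosome and cell cycle lists higher relative to the other genes. None of 73 cytosolic ribosomal protein genes passed, but 65 had a fold change above 0, with a median of 0.18 (camera adjusted p = 2.96e-06). Rpl13 differed by 0.12 (-0.14 with the T cell covariate), and the list, called in 14 of 16 other settings, had adjusted p = 0.740 with an estimated correlation. Hmgb2 and Rrm2, a subunit of ribonucleotide reductase, rose by 0.71 and 0.89, and were 2 of 29 cell cycle genes, with 2 higher adjusted over the list alone (camera adjusted p = 0.0272, and adjusted p = 0.740 with an estimated correlation). The cell cycle list was called in 7 of 16 other settings, with adjusted p = 0.113 under quantile normalization and 0.400 without both H2 and N2. The call of Hmgb2 ended without H1, H3, N2 or N3 (adjusted p up to 0.0611) and that of Rrm2 without H1, H3, H4 or N2 (up to 0.0923).

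**Figure D2:**
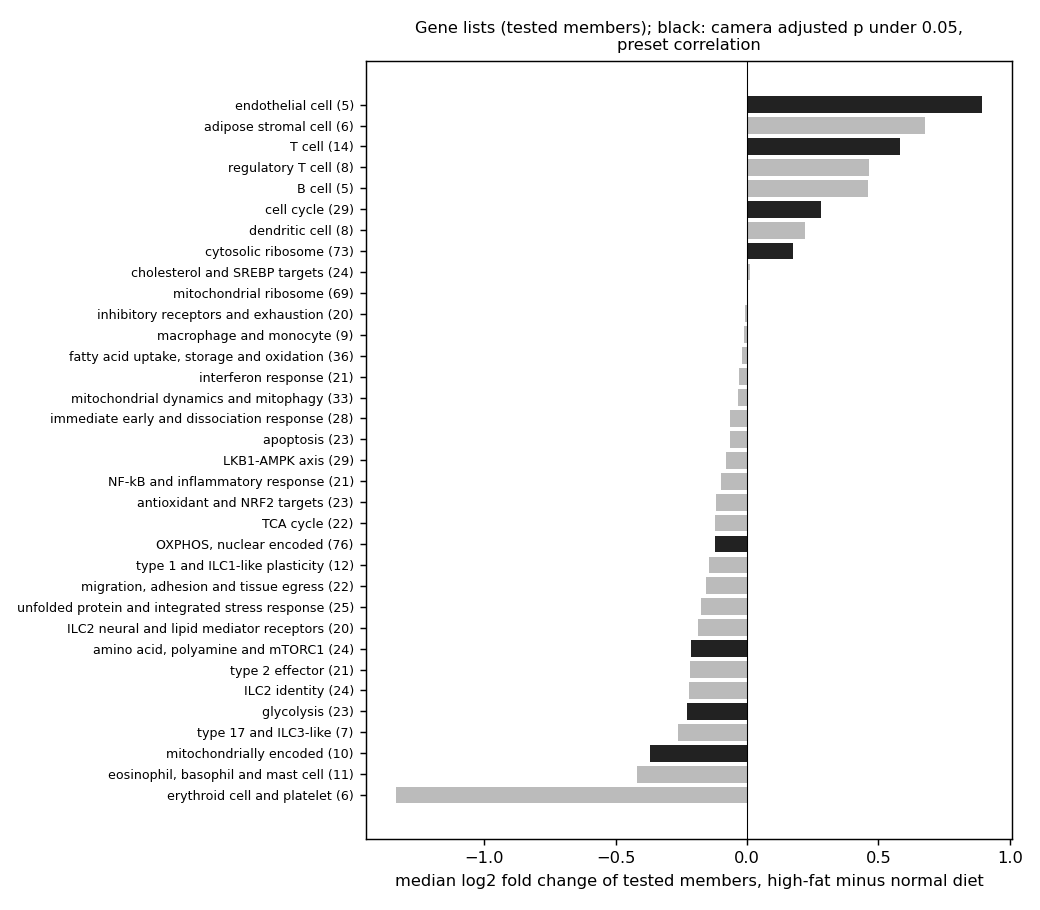
Median log2 fold change, high-fat minus normal diet, of the tested members of each of 34 gene lists, with the number of tested members in brackets. Black bars are the 8 lists past the threshold of camera with the preset correlation, 4 higher and 4 lower, and none of them passed with an estimated correlation.

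In all, 8 of 34 tested lists shifted under camera with the preset correlation. None passed with an estimated correlation (lowest adjusted p = 0.443, 1 list at an unadjusted p under 0.05). None shifted in 1 direction by fry, the rotation test of limma (lowest adjusted p = 0.0691, 4 lists at an unadjusted p under 0.05). Of the 8 lists, the mixed test of fry gave adjusted p = 4.19e-07 for glycolysis, 3.10e-05 for nutrient genes, 0.00215 for cell cycle and 0.00582 for endothelial cells. It gave 0.157 for the cytosolic ribosome, 0.229 for oxidative phosphorylation, 0.183 for mitochondrially encoded genes and 0.0963 for T cells. Outside these 8 lists, most tested lists also passed the mixed test. Among them were cholesterol and SREBP targets (0.000151), type 17 genes (4.06e-05) and apoptosis (3.08e-05). A low adjusted p of the mixed test therefore does not set a list apart. Quantile normalization left 4 lists. Median, mean and camera direction did not share a sign for the lists of fatty acid handling, cholesterol, mitochondrial ribosome, inhibitory receptors, type 17 genes, interferon response and macrophages.

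Some transcripts of endothelial cells were higher on the high-fat diet. Esam, an endothelial adhesion molecule, went from 0.763 ± 0.409 to 4.96 ± 2.52 FPKM (log2 fold change 1.67, adjusted p = 0.0111) and Vwf, the clotting factor of endothelium, from 3.03 ± 1.33 to 7.24 ± 2.26 FPKM (1.04, adjusted p = 0.0428). Of the 14 members of the endothelial list 5 were tested, and the rest lay under the filter. All 5 tested members had a fold change above 0 (2 called, 3 adjusted over the list alone), with camera adjusted p = 0.00169 and adjusted p = 0.443 with an estimated correlation. The call of Vwf ended without H2, H3, H4, N1, N2 or N4 (adjusted p up to 0.126). Class II genes of the dendritic cell list rose, H2-Eb1 from 4.03 ± 0.83 to 15.2 ± 3.90 FPKM (1.67, adjusted p = 0.00114), H2-Aa by 1.63 and H2-Ab1 by 1.53. In that list 3 of 8 genes rose while 2 fell (4 higher and 3 lower adjusted over the list alone), among them Zbtb46, a transcription factor of dendritic cells and endothelium, by 1.34 (adjusted p = 0.00212, and camera adjusted p = 0.427 for the list). The other was Xcr1, a chemokine receptor, chosen after its values were seen, which fell by 0.79. In the macrophage list Ctss rose by 0.80 and Cd9 fell by 0.59 among 9 genes, calls that ended without H1, H3, H4, N2 or N3 (adjusted p up to 0.0908) and without any single library (up to 0.132). That of H2-Ab1 ended without H1, H4, N1 or N3 (up to 0.0806).

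Camera called the T cell list higher, with no member called. The mean log2 value of the 14 tested T cell genes was 5.10 ± 0.44 on the high-fat diet and 4.52 ± 0.45 on the normal diet (SD, n = 4 each, exact two-sided permutation p = 0.0857, where 4 against 4 can give 0.0286). Camera gave the list adjusted p = 0.00143 (adjusted p = 0.740 with an estimated correlation), and 1 member passed when adjusted over the list alone. Trbc1 and Trbc2, constant genes of the T cell receptor, were abundant on both diets, at 392 ± 49.3 and 541 ± 147 FPKM for Trbc1 and 255 ± 33.7 and 350 ± 99.5 FPKM for Trbc2. Other T cell genes, chosen after their values were seen, lay lower and did not pass. Cd3g was at 112 ± 19.0 and 140 ± 51.0 FPKM and Cd3e at 5.14 ± 4.30 and 11.7 ± 3.41 FPKM. Cd3d was at 4.28 ± 4.50 and 8.33 ± 2.59 FPKM and Cd4 at 6.26 ± 6.43 and 11.6 ± 6.38 FPKM. With levels so unlike, the abundance of Trbc1 and Trbc2 does not show how many T cells were present. In the mean of the 14 genes, N4 lay among the high-fat libraries, at 5.19. Of 8 regulatory T cell genes Il2ra was the only call, lower (2 higher and 2 lower adjusted over the list alone), while 6 had a fold change above 0 and camera pointed upward (adjusted p = 0.221, past the threshold in 2 of 16 other settings). Ctla4 and Foxp3, chosen after their values were seen, were at 11.4 ± 8.24 and 34.4 ± 14.998 FPKM and at 4.51 ± 4.72 and 9.96 ± 4.86 FPKM, and did not pass (adjusted p = 0.116 and 0.302).

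Mast cell transcripts were abundant in every library, and none was called. Tpsb2, a mast cell tryptase, was at 4007 ± 1172 FPKM on the normal diet and 2919 ± 1571 FPKM on the high-fat diet (log2 fold change -0.62, adjusted p = 0.588), and Cma1, a chymase, at 1257 ± 526 and 1029 ± 551 FPKM. The list of eosinophil, basophil and mast cell genes had no call among 11 (camera adjusted p = 0.293, and called in 1 of 16 other settings). H2 held the lowest values, with Tpsb2 at 966 FPKM. Haemoglobin transcripts varied over a wide range within the normal diet, with Hbb-bs at 0.617 to 796 FPKM and Hba-a1 at 131 to 2755 FPKM, and their list had no call (camera adjusted p = 0.0968, median log2 fold change -1.34), though camera called it lower in 6 of 16 other settings. Neither did the B cell list, with Igkc at 4.61 to 636 FPKM over the libraries and Ighm at -0.13 (camera adjusted p = 0.293), or the adipose stromal list, with Gsn at 0.85 and Dpp4 at -0.22 (camera adjusted p = 0.154, and called higher in 3 of 14 other settings). The adipocyte, natural killer, mesothelial and neutrophil lists had 4, 2, 2 and 1 tested members and were not tested as lists. The adipocyte members called were Fabp4 and Pparg, and the natural killer list held Txk. Lrrn4 and Igfbp6 of the mesothelial list and S100a9 of the neutrophil list differed by -0.18, -0.01 and 0.10.

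**Figure D3:**
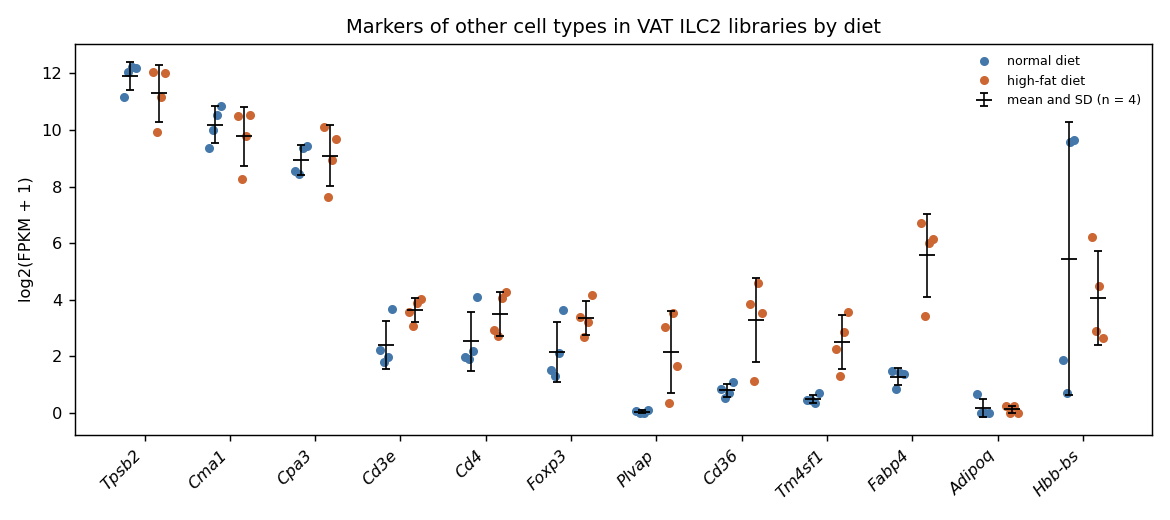
Values of 12 markers of other cell types in the 8 libraries, with log2(FPKM + 1) on the vertical axis. Blue points are the 4 normal-diet libraries and orange points the 4 high-fat libraries, with the mean and SD in black. Tpsb2 lies between 966 and 4844 FPKM in all 8 libraries, and Adipoq averages 0.0853 FPKM in the high-fat libraries.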

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

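The comparison of each library with its group was planned before the data were examined. In 9 of 198 groups of 4 libraries, over the named genes and 5 measures of the libraries, the highest or lowest library stood apart from the other 3 by a larger part of the group's range than Dixon's 95% critical value. Chance gives about 9.9 such groups. In high-fat library 1 Fbxl21 was high (10.8 FPKM against 6.98 to 7.42, gap 0.884 of the range). In high-fat library 2 Dgat1 was high (2206 FPKM against 1158 to 1337, gap 0.8291) and Prkaa1 low (6.12 against 9.37 to 10.02, gap 0.835). Rrm2 was high in high-fat library 3 (11.9 FPKM against 9.39 to 9.56, gap 0.932), and Pparg low in high-fat library 4 (46.5 against 51.5 to 52.1, gap 0.892). On the normal diet, library 1 had Lrrn4 high (4.56 FPKM against 2.80 to 3.09, gap 0.836) and Il7r low (150 against 193 to 199, gap 0.872). Library 2 of that diet had Mdh2 high (433 FPKM against 242 to 273, gap 0.839) and Itgb1 high (61.1 against 49.0 to 49.97, gap 0.923).

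The genes with values below 0, which the comparison of the diets leaves out, also hold signal: 2037 of them had at least 10 recovered reads in 4 or more libraries.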

How the results depend on the processing

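The factor divided out, the test on recovered reads, both libraries 2 left out and the covariates were chosen after seeing the data, and the other settings before. The test of the report called 328 genes (112 higher, 216 lower). Array weights gave 649 (272 higher, 377 lower), the factor divided out 571 (185, 386), the mast cell covariate 623 (278, 345), limma voom on recovered reads 904 (344, 560) and the T cell covariate 29 (8, 21). No filter gave 130 genes (41, 89), with 24107 genes tested. Quantile normalization gave 226 higher and 204 lower, and equal medians 172 higher and 305 lower. The stricter filter, with 7502 genes tested, gave 331 lower and limma without trend and robust 132 lower. Without both libraries 2 there were 472 genes, 250 of them higher. With single libraries left out, 129 to 535 genes passed, 38 to 248 higher and 91 to 287 lower. For gene lists, 8 in the report, camera with an estimated correlation gave 0, fry for a shift in 1 direction 0 and quantile normalization 4. The T cell covariate raised the median standard error of the called genes 1.24-fold and left 0.912 of the fold change. The cause of the other shifts was not tested.

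The replicate numbers are shared by the diets, but same-numbered libraries did not deviate together. Their correlations ran from -0.255 to 0.0783 and 0 of the 8 libraries correlated best with their own number, so the values showed no pairing by number. The labels do not say what a shared number stands for, and a shared origin is not excluded. With the replicate block 191 genes passed (78 higher, 113 lower) and 10 lists.

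Of the 60 called named genes, 60 kept their direction under every setting run, 27 stayed past the threshold with each library left out and 9 under all alternatives: Il5, Slc16a3, Tgm2, Zbtb46, Srxn1, Pmaip1, Tcf7, Ubash3a and H2-Eb1. The T cell covariate ended 51 of the 60 calls, no filter 27, the replicate block 21, limma without trend and robust 17, leaving out both libraries 2 ended 11, quantile normalization 8, the test on recovered reads 3 (Fabp4, Egr3 and Cd9) and equal medians 1. With the T cell covariate set aside, 24 genes held under all the others. The sign turned in 12 named genes, none of them called in the report or under the setting that turned it. Quantile normalization gave 0.15 for Sik1, 0.16 for Atp5b, 0.0299 for Cox6a1, 0.0137 for Sdhb, 0.0274 for Psmb8, -0.00591 for S100a9 and 0.046 for Ighm. Equal medians gave 0.000185 for Sik1. Array weights gave 0.00605 for Atp5b and -0.0292 for S100a9. The factor divided out gave 0.0485 for Sik1 and 0.0155 for Igfbp6. Leaving out both libraries 2 gave 0.0691 for Atp5b, 0.0478 for Sdhb, 0.00409 for Psmb8, 0.0187 for Cma1, 0.00216 for Ighm and 0.0126 for Igfbp6. The mast cell covariate gave 8.63e-05 for Sik1, 0.0556 for Atp5b and 0.0454 for Igfbp6. The T cell covariate gave -0.14 for Rpl13. The test on recovered reads gave 0.0696 for Sik1 and 0.0237 for Igfbp6. With single libraries left out, the range was Sik1 -0.12 to 0.086, Igkc -0.14 to 1.96, Atp5b -0.10 to 0.11, S100a9 -0.0639 to 0.22, Cma1 -0.69 to 0.0828, Ighm -0.37 to 0.20, Igfbp6 -0.11 to 0.13 and Hbb-bs -2.97 to 0.0147. Library depth was 9005363 to 15752815 reads, and the filter left genes such as Ifng and Ppargc1a out of the main test. The setting without a filter included them, but its results for them are not given here.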

Other observations

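The tests of endothelial, adipocyte and mast cell RNA and the test of T cell RNA for the rises were chosen after values had been seen. So were the test on recovered reads and the genes named in the next 2 paragraphs. The factor divided out and the T cell covariate, also used below, are settings added after seeing the data as well.

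Genes with values below 0 could be tested on recovered reads, where limma voom called 50 of 2037 (16 higher, 34 lower). Neat1, a nuclear RNA that builds paraspeckles, fell from 348 ± 11.5 to 220 ± 10.99 CPM (reads scaled to library size, SD, n = 4 each), with adjusted p = 0.000885. Lilr4b, the close paralog of Lilrb4a, fell from 1809 ± 159 to 1035 ± 115 CPM (log2 fold change -0.81, adjusted p = 0.000474). Slc5a3, a carrier of myo-inositol, fell by 0.75 (adjusted p = 0.0379). Bcl2a1d, of an anti-apoptotic family of near-identical copies, rose by 0.43 (adjusted p = 0.0406), and Mndal, of an interferon-inducible family, by 0.66 (adjusted p = 0.00846).

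Outside the named genes, Cav1, a coat protein of caveolae, was at 1.07 ± 0.561 FPKM on the normal diet and 12.7 ± 8.42 FPKM on the high-fat diet (SD, n = 4 each, adjusted p = 0.122), with H2 at 1.52 FPKM, under the 1.71 FPKM of N2. Cd36, a fatty acid transporter, was at 0.753 ± 0.288 and 12.05 ± 9.01 FPKM (adjusted p = 0.119), with H2 at 1.19 FPKM. Tm4sf1, an endothelial membrane protein, rose by 2.01 on the log2 scale (adjusted p = 0.0191), and Id3, an inhibitor of helix-loop-helix factors, by 1.94 (adjusted p = 0.00431).

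Could the calls come from the way the values were made or from chance? Of the called genes, 97.3% passed in the same direction with the recycled factor divided out, and 93.1% of those with enough reads passed on recovered reads, where depth is part of the model. The first value argues against the factor that repeats down the rows as the source of the calls. That setting leaves the factor in each library's overall divisor. The second, with library sizes taken from the reads, shows that most of those calls held under another scaling of library size. Both tests scale the same 8 libraries, so it cannot argue against an effect of depth that scaling leaves. The 8 libraries can be split into 4 and 4 in 35 ways. Only the real split (1) gave as many as 328 genes, and the highest other gave 9. In 1 direction the real split (1) gave 112 higher and 216 lower, and the highest other gave 6. These counts argue against chance alone, but 35 splits cannot give an exact permutation p under 0.0286, so chance is not excluded. Every other split mixes the diets, which widens the spread within its groups if the diets differ. Nor can the splits speak to chance between animals if libraries share animals or pools, which the labels leave open. The list count does not stand apart in this way, since 5 of the 35 splits called 8 or more and the highest other called 9.

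The rise of endothelial transcripts may come from RNA of endothelial cells in the high-fat libraries. In a further set of endothelial genes, written down after values of some of them had been seen and sharing Cd36, Calcrl, S1pr1 and Ets1 with other lists, 20 were tested, 17 had a fold change above 0, 5 were called higher and 0 lower, with a median log2 fold change of 0.689. Since the set was drawn up with some of these values in view, it could not test that explanation, which stays open. For adipocyte RNA the first test took the highest high-fat mean among 6 adipocyte transcripts and left it open, at 3.30 FPKM for Lipe (2.54 FPKM on the normal diet). The test put in its place set Adipoq against Fabp4 in the high-fat libraries and found 0.139% of its level (0.0853 against 61.3 FPKM). Adipoq was among those 6 transcripts, so its value was known before, and it could not serve as a test of the explanation. As a description, the high-fat libraries held almost no Adipoq beside Fabp4. Whether endothelial cells passed the sort, whose gate the labels do not describe, or ILC2s expressed these genes on the high-fat diet stays open.

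Cells of other types could also move the called genes. For mast cells the first test, the mean difference of their abundant transcripts (-0.42, standard error 0.476) against the median of the falls (-0.81), decided nothing. The test put in its place took the mast cell mean as a covariate. With it 100% of the genes called lower and 100% of those called higher kept at least 0.8 of their fold change. That mean was 6.78 ± 0.91 on the high-fat diet and 7.06 ± 0.40 on the normal diet (SD, exact two-sided permutation p = 0.686). A covariate that differs so little between the diets can hardly move the fold changes, so this test cannot argue against mast cell RNA. Changes within mast cells were not tested. With the T cell mean as a covariate 82.9% of the genes called lower kept at least 0.8 of their fold change. So far as that mean follows T cells, this argues against them as the whole cause of the falls, Il5 included (-1.82, standard error 0.20, against -2.06 and 0.17). Only 25 of the 328 calls remained. The median standard error rose 1.24-fold and 0.912 of the fold change was left, and what ended the calls was not tested. Of the genes called higher 62.5% kept at least 0.8 of their fold change. For the rises a larger share of T cells and a change within ILC2s cannot be told apart, because the T cell mean goes in part with diet in these libraries (exact two-sided permutation p = 0.0857). An effect of diet on ILC2s stays among the open explanations and was not tested apart from these.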
